A study of Mus musculus with 8 samples.

How the data were processed

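Smooth muscle cells of the mouse ascending aorta were profiled by droplet single-cell RNA sequencing (10x Genomics Chromium). Per the labels, the aorta was digested and GFP-positive cells were sorted as smooth muscle cells. The 8 libraries came from 2 genotypes, Apoe-deficient mice (called Apoe here) and Apoe-deficient mice with a Tgfbr2 knockout specific to smooth muscle (called KO), each on 4 diets: the diet labelled ND and a high fat diet (HFD) for 1, 2 or 4 months (1M, 2M and 4M). Each genotype and diet had 1 library, so cells were never treated as replicates. Cells whose names carried "dko" were matched to the KO libraries by the diet in their names and titles, and 0 cells were left without a library.

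The deposited values are log2 values, scaled per cell with trimmed-mean (TMM) factors by the authors, per the file names. The submitters' processing notes list UMI-tools, STAR, featureCounts and Subread 1.6.0, with the genome build GRCm38. The annotation release used by the authors is not given in the sources used here. The data come in 6 tables: 1 time-course table per genotype and 1 table per diet with both genotypes. Each library is therefore in 2 tables, with the same barcodes and 0 entries that differ once scaled back, but scaled separately (median ratio of the cell scales from 0.932 for KO 2M to 1.12 for Apoe ND). Each test used values from 1 kind of table: the diet tables for the genotype effect, the time-course tables for slopes. The 2 time-course tables were normalized separately, so genotypes in a slope fit have their own level terms.

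For every entry, 2 to the power of the value, minus 1, was a whole multiple of the smallest such value in its cell (100% of entries, tolerance 0.01), which gives whole unique molecular identifier (UMI) counts. Levels are given as these UMIs per 1000000 UMIs of the library (CPM), with exact Poisson 95% intervals, and shares of cells with exact binomial (Clopper-Pearson) 95% intervals. Both kinds of interval cover counting error only. In each library a gene seen in under 5% of cells is listed at 0 (lowest listed share 5.00%), and no CPM level, fold or bound is given against such a listing. In the fits below such a listing enters as a value of 0. Effects and slopes of a gene listed at 0 in some libraries therefore rest partly on it. Some transcripts of the mitochondrial genome are also listed at 0 (mt-Co3 has values in 3 of the 8 libraries), so a listing at 0 need not mean low expression. Per the file names, Apoe and Tgfbr2 were removed from the tables. Tgfbr2 is still listed in the Apoe time-course table. The tables list 11447 gene identifiers, of which 11439 matched the GENCODE annotation vM21 of GRCm38 without their version. Symbols and 1-based coordinates are from that annotation.

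The libraries held 13056 cells in all, from 1127 (KO ND) to 2659 (Apoe 2M), with total UMIs from 9407155 (Apoe 4M) to 19719335 (Apoe 2M). The lowest count in a cell was 2905 UMIs and no cell had under 500 genes, so no cell was removed. No doublet caller was run. Cells with 3 or more markers of macrophages, endothelial cells, lymphocytes or Schwann cells numbered 84 in KO 1M, 2 in KO 2M, 56 in KO 4M and 0 elsewhere. Only listed markers could count, so a 0 does not show that such cells were absent.

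The design planned a count test for counts and a test of mean log values per library for logs. Since the tables hold logs, the mean log2 value per library was tested with limma 3.58.1 in R 4.3.3, on 9253 genes seen in at least 5% of cells on average over the 8 libraries. Effects are differences of mean log2 values over cells, zeros included, and are not folds. The genotype effect had diet as a factor (3 residual degrees of freedom). The slope per month had genotype as a factor (5 residual degrees of freedom), and the difference of slopes and the slopes within genotypes came from a fit with both slopes (4 residual degrees of freedom). The error in these fits is the spread of libraries around an additive or linear model, and nothing in the labels says how many animals a library held. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. For a single diet the difference of log2(mean per 1000000 + 1) is given with no test. There, genes count when they are listed in both libraries and differ by at least 1.

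The fits were tested on simulated data with 200 changed genes among the 9253. For the genotype effect 79.1%, 89.6% and 100% of genes changed by 0.5, 1 and 2 were recovered, with 11 false calls. For the slope 88.1%, 97.0% and 100% were recovered at 0.2, 0.5 and 1, with 13 false calls. For the difference of slopes the shares were 76.1%, 91.0% and 98.5%, with 14 false calls. The simulated noise was independent between genes, and no library was made to stand apart. These shares therefore do not measure how many changed genes the fits find in the real data.

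The design, the gene lists, the cell type markers, the rule for named genes and most of the alternatives were chosen before the data were examined. Of 23 lists, 17 had at least 3 measured genes and were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over lists. For single diets the median of a list is placed among 10000 random lists of the same size matched on mean level in 20 bins. This was planned over genes listed in either library and was limited to genes listed in both after the planned values were seen. Named genes were the 10 highest and 10 lowest past the threshold for the genotype effect (same sign on all 4 diets) and the slope, filled up with genes of a constant sign where fewer passed. For single diets, slopes within a genotype and their difference the 5 highest and 5 lowest were named, then up to 4 members per list and a fixed set of markers. The naming of single-diet genes over genes listed in both libraries was added later.

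Cells of each table were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). Leading genes of a cluster were ranked by fold of UMIs per 10000 (1 added to both sides) against the other cells of the table, among genes in at least 10% of its cells. The rule that turns markers into a name (3 markers or more, and no other class ahead) was set after the clusters were seen. For comparisons of shares of cells each cell was also thinned to 2900 UMIs, which kept all cells. Mixing of libraries was measured as the percent of the 15 nearest neighbours of a cell that came from its own library. Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

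Alternatives covered pseudocounts of 0.1, 1 and 10 per 1000000 on linear means, filters on low genes (none and 20% of cells), trimmed-mean factors, values not rescaled, robust limma, cells with other-type markers left out, libraries left out, the other table of each library, other time scales, UMI sums, thinned cells, genes listed in all 8 libraries, and other cluster settings. Not used here were the levels of Apoe, which no table lists. The result of 1 gene is not reported here, though counts and list tests include it.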

Results

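GFP-positive smooth muscle cells of the ascending aorta were compared between Apoe mice and KO mice, Apoe-deficient animals that also lack Tgfbr2, a receptor for TGF-beta, in smooth muscle. Apoe-deficient mice develop high plasma cholesterol and atherosclerosis on a high fat diet. The Apoe libraries held 1415 cells (ND), 1488 (1M), 2659 (2M) and 1235 (4M), with 13362860, 13955036, 19719335 and 9407155 total UMIs. The KO libraries held 1127, 1302, 2253 and 1577 cells, with 12337547, 11977077, 18254302 and 18301826 total UMIs. The median cell had between 6966 UMIs (Apoe 4M) and 10988 UMIs (KO 4M), so the 4M pair differed most in depth. Each genotype and diet had 1 library, and values of a single library have no replicate error.

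The targeted gene came first. Tgfbr2 (chromosome 9, 116084293 to 116175360, minus strand, GRCm38) was listed in the Apoe time-course table alone, at 43.6, 42.1, 39.3 and 54.6 UMIs per 1000000 UMIs of the library (CPM) in Apoe ND, 1M, 2M and 4M. A Tgfbr2 UMI was seen in 24.4% to 32.9% of the cells of these libraries. No KO library has a Tgfbr2 value in the tables, and Apoe is in no table, so neither label could be checked from the targeted gene.

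The comparison of genotypes over the 4 diets asked how loss of Tgfbr2 alters smooth muscle cells. The mean log2 value of Eln (elastin, the core of the elastic fibre; chromosome 5, 134702593 to 134747323) fell by 2.74 ± 0.07 (SE, 4 diets). Mfap4, a protein of elastic fibres, fell by 3.28 ± 0.18 (listed at 0 in KO 4M), and Fbln5 (fibulin 5, which assembles elastic fibres) fell by 2.41 ± 0.15. Eln stood at 3436, 1899, 2362 and 1717 CPM in the Apoe libraries from ND to 4M, and at 714, 574, 368 and 54.97 in the KO libraries. The small SE of Eln holds for mean log2 values only, since the ratio in CPM was far larger at 4M than on the other diets. Over 18 other settings Eln kept its sign and passed the threshold in 9. Mfap5, a microfibril protein, fell by 1.11 ± 0.05 and Lox, which crosslinks elastin and collagen, by 0.86 ± 0.03.

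Pmepa1, a target and feedback inhibitor of TGF-beta signalling, fell by 1.74 ± 0.08. Pmepa1 stood at 472, 454, 457 and 631 CPM in Apoe and at 49.9, 84.3, 60.3 and 39.9 in KO. Pdlim1 fell by 1.11 ± 0.04, and Mylk4 (listed at 0 in KO 4M), Hspa2, Ptprz1 and Fam210a fell by 0.58, 0.48, 0.41 and 0.21. Anxa1 (annexin A1) rose by 0.39 ± 0.02, from 257 to 396 CPM in Apoe to 425 to 566 in KO. Nudc-ps1, a processed pseudogene that can share reads with its parent gene, rose by 0.43 (listed at 0 in Apoe 2M) and is uncertain.

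By limma, 14 of 9253 genes passed an adjusted p of 0.05, 2 higher and 12 lower, and each had the same sign on all 4 diets. The adjusted p was 0.0149 for Eln, 0.0307 for Mfap4, 0.0439 for Fbln5, 0.0209 for Pmepa1, 0.0163 for Lox, Pdlim1 and Anxa1, 0.0209 for Ptprz1, 0.0222 for Mfap5, 0.0307 for Hspa2 and Nudc-ps1, 0.0402 for Mylk4 and 0.0482 for Fam210a. An unadjusted p under 0.05 was reached by 1298 genes. On the scale of linear means per 1000000 plus 1, 4 genes passed (1 higher, 3 lower), 0 of them among the 14, and with values not rescaled 11 passed (4 higher, 7 lower), 1 of them among the 14. Of the 9 genes that passed with 0.1 added, the 4 with trimmed-mean factors and the 1 on recovered UMI sums, 0 were among the 14. Without the 4M libraries 240 genes passed (90 higher, 150 lower), including the 14, while without the ND libraries 1 passed and without the 1M or the 2M libraries 0 passed.

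**Figure D1:**
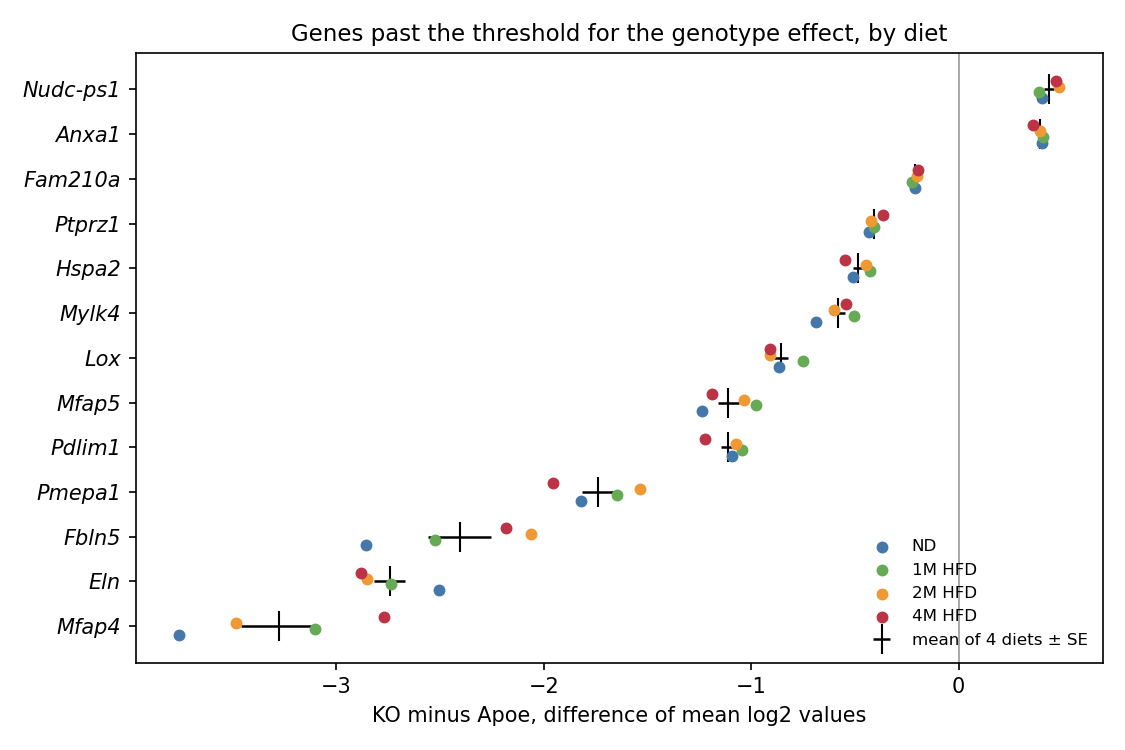
Difference of mean log2 values, KO minus Apoe (x axis), for 13 genes past the threshold (y axis). Dots are the 4 diets and crosses the mean of the diets ± SE; all 4 dots of a gene lie on the same side of 0, from Mfap4 with a mean of -3.28 to Nudc-ps1 with a mean of 0.43.

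Genes that were higher in KO on every diet without passing the test included Lgals3 (galectin 3), with a difference of 1.24 ± 0.55 (adjusted p = 0.426, limma). Tmem176b differed by 0.57 ± 0.04 (0.0692, limma) but was listed at 0 in Apoe ND and Apoe 1M. Others were Sdcbp with 0.55 ± 0.05 (0.0952), Gja1 (connexin 43) with 0.55 ± 0.10 (0.170) and Rexo2 with 0.52 ± 0.09 (0.158, limma). Emb, Emp3 and Pdcd5-ps differed by 0.48, 0.44 and 0.51 (adjusted p from 0.1004 to 0.157, limma).

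Of the fixed gene lists, the extracellular matrix list was lower in KO than other genes (camera, adjusted p = 4.9e-08; adjusted p = 0.0799 with an estimated correlation). Of its 25 measured members 5 fell and 0 rose, and 7 fell when adjusted over the list alone. The TGF-beta-responsive list was lower (adjusted p = 1.0e-05; adjusted p = 0.0799 with an estimated correlation), with 2 of 18 members past the threshold over all genes and 7 when adjusted over the list alone. Ccn2 of that list (connective tissue growth factor) differed by -1.43 ± 0.20 (adjusted p = 0.157, limma). The dissociation and stress response list, early response genes induced by tissue digestion among others, was lower (adjusted p = 8.9e-12; adjusted p = 0.0799 with an estimated correlation). All 17 members were lower in KO, 0 passed over all genes and 10 passed when adjusted over the list alone. Fos differed by -1.19 ± 0.26, Fosb by -0.82 ± 0.06 and Egr1 by -0.71 ± 0.11. For these 3 lists fry, which asks whether the members move 1 way on balance, gave an adjusted p of 0.00710, 0.00627 and 0.00627.

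The oxidative phosphorylation list was higher in KO than other genes (camera, adjusted p = 0.00312), with all 14 members higher in KO, 0 past the threshold and 1 when adjusted over the list alone; the adjusted p = 0.457 with an estimated correlation. The contractile list was lower (adjusted p = 0.0230), with 15 of 17 members lower and 0 past the threshold; the adjusted p = 0.871 with an estimated correlation. This sign came from the 4M pair, since the median of single-diet differences was above 0 on the other 3 diets. The other 12 lists did not pass. Their adjusted p was 0.108 for chondrocyte and bone and for pericyte, 0.116 for interferon response, 0.123 for fibroblast and for matrix-degrading, 0.753 for inflammatory, cholesterol synthesis, mesenchymal stem cell, mitochondrial genome and unfolded protein response, and 0.793 for adipocyte and for lipid handling.

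On ND, 1M and 2M the genotype difference had a similar make-up. The correlation of the differences across genes, which are not independent replicates, was 0.695 to 0.760 between these diets. In KO ND, Mfap4 differed from Apoe ND by -5.11 on the scale of log2(mean per 1000000 + 1), Fbln5 by -4.10, Pmepa1 by -3.24 and Nupr1 by -3.11, while Itih4 was higher by 2.67, Adra1b by 2.64, Sncg by 2.52 and Kcnk3 by 2.18. In KO 1M, Heyl, a Notch target, differed by -2.90, Fbln5 by -2.85, Mfap4 by -2.64, Bmp3 by -2.57 and Sparcl1 by -2.55, and Smoc2 was higher by 2.66, Cxcl1 by 2.45, Dcn (decorin) by 2.31 and Ifi27l2a by 2.19. In KO 2M, Mfap4 differed by -4.24, Mylk4 by -3.14, Pmepa1 by -2.96, Heyl by -2.77 and Eln by -2.73, and Dcn was higher by 5.37, Lum (lumican) by 4.31, Comp by 3.48, Sncg by 3.001 and Rarres1 by 2.98. Gm10093 and Gm13340 (higher on ND and 1M, by 3.15 and 3.48) and Gm4149 (by -3.82 on ND) also met the rule; such predicted genes can share reads with copies elsewhere.

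The number of genes listed in both libraries that differed by at least 1 was 197 on ND (69 higher in KO, 128 lower, of 8281), 146 on 1M (69 and 77, of 7865) and 278 on 2M (99 and 179, of 7378). Each is a difference between 2 libraries and carries no test. Medians of the extracellular matrix list were -0.38, -0.70 and -0.78, at or below percentile 0.010 of 10000 random lists, and those of the TGF-beta-responsive list were -0.37, -0.19 and -0.58 (percentiles 0.010, 0.335 and 0). The dissociation and stress response list stood at -0.48, -0.34 and -0.60 (percentile 0 on each). Interferon response genes were higher in KO, with medians of 0.51, 0.64 and 1.12 (percentile 100 on each); Ifitm3 was higher by 1.70, 1.23 and 1.55. The inflammatory list was also high, over 4, 5 and 6 listed genes (0.64, 0.55 and 0.73, percentiles from 99.9 to 100). The fibroblast list, markers of another cell type, differed more, with medians of -0.47 on ND (percentile 0.970), 2.06 on 1M (100) and 1.37 on 2M (99.99), over 4, 4 and 5 genes, and the chondrocyte and bone list stood at 0.50 (99.955) on 2M. On 1M all 8 macrophage markers listed in either library had values in KO, and of these only Lgals3 had a value in Apoe 1M; KO 1M held 84 cells with 3 or more markers of another cell type. The contractile list was slightly higher in KO, with medians of 0.30, 0.18 and 0.17 (percentiles 99.9, 99.6 and 91.1).

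**Figure D2:**
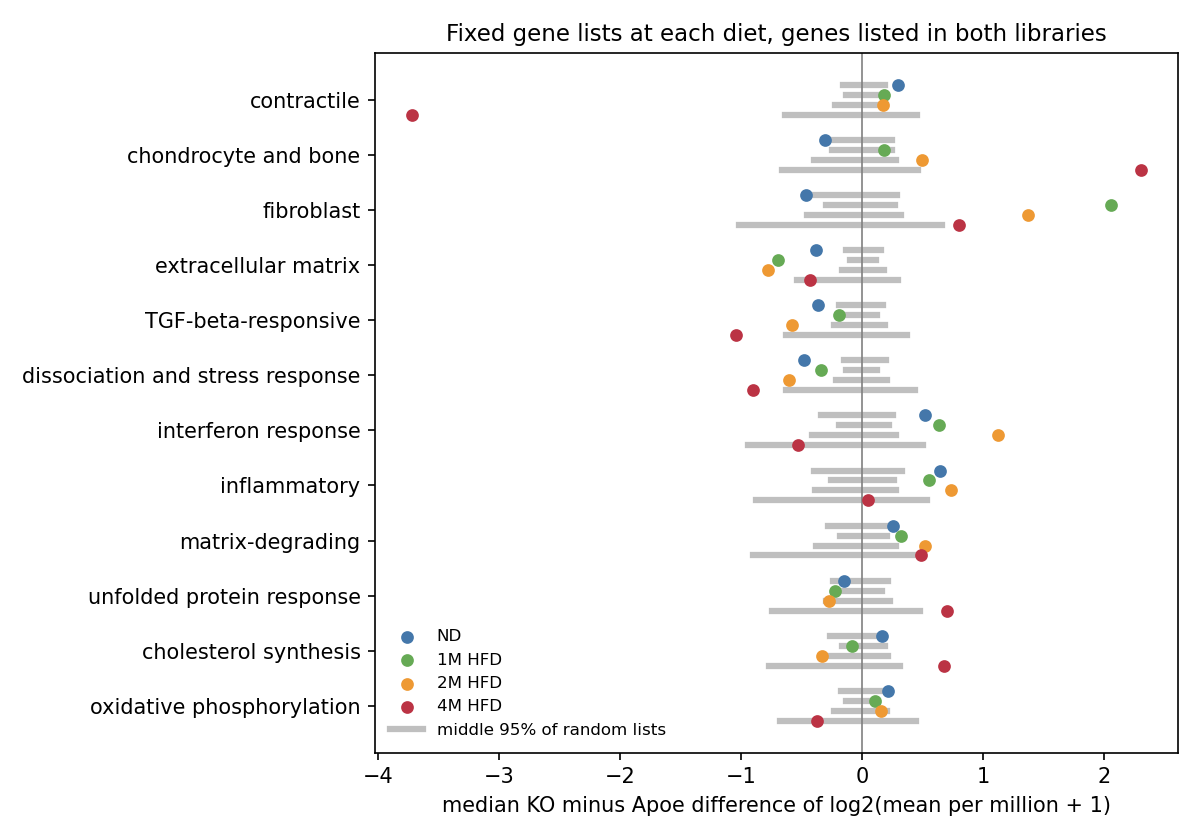
Median KO minus Apoe difference of log2(mean per 1000000 + 1) (x axis) for 12 fixed lists (y axis), over genes listed in both libraries of a diet. Dots are diets, with 1 library per genotype, and grey bars span the middle 95% of random lists; at 4M the contractile list lies at -3.72 and the chondrocyte and bone list at 2.30.

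The 4M pair differed from the other 3. Contractile genes were far lower in KO 4M: Acta2, smooth muscle actin, stood at 802 CPM (95% interval 789 to 815) against 11932 in Apoe 4M (11862 to 12002), Myh11, smooth muscle myosin, at 74.4 against 1639, Cnn1 (calponin) at 91.5 against 1221 and Tagln (transgelin) at 19.6 against 835. Genes of cartilage and bone were higher: Col2a1, the main collagen of cartilage, stood at 11749 (11700 to 11799) against 2545 (2513 to 2578), Chad (chondroadherin) at 5880 against 993, Spp1 (osteopontin) at 5299 against 1090, Acan (aggrecan) at 817 against 148 and the cartilage transcription factor Sox9 at 626 against 186. Among genes listed in both libraries Cnmd (chondromodulin) had the largest difference, 7.18, before Cd24a (5.07), Snorc (5.06), Prg4 (4.96) and Chadl (4.96). The lowest were Sost (-5.34), Tagln (-5.14), Fblim1 (-5.13), Eln (-4.98) and Efhd1 (-4.91).

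Bglap (osteocalcin), Bglap2, Otor, Col9a2 and Col11a1 were listed in KO 4M, with Bglap at 3031 CPM, and listed at 0 in Apoe 4M. Mfap4, Nox4, Kcnmb1, Heyl and 2210407C18Rik were listed in Apoe 4M and listed at 0 in KO 4M. In all, 1964 of 7852 genes listed in both differed by at least 1 (584 higher, 1380 lower). The contractile list had a median of -3.72 over 15 listed members (percentile 0) and the chondrocyte and bone list one of 2.30 over 15 (percentile 100). The pericyte list stood at -2.04 (percentile 0.165), the TGF-beta-responsive list at -1.05 (0.1), the stress list at -0.91 (0.195), the extracellular matrix list at -0.43 (6.98; 10 members higher and 14 lower of 24), the unfolded protein response list at 0.70 (99.6), the cholesterol synthesis list at 0.67 (99.9) and the fibroblast list at 0.80 (98.8). The interferon response list stood at -0.53 (15.7) and the mitochondrial genome list at -0.95 (2.82; 7 listed members). On ND, 1M and 2M the unfolded protein response list had stood at -0.15, -0.23 and -0.27 (percentiles 8.81, 0.67 and 3.49). The cholesterol synthesis list had stood at 0.16, -0.09 and -0.33 there (97.7, 12.3 and 2.685). Across genes, the 4M differences correlated with those of the other diets at 0.0747 to 0.198. Cells with 3 or more markers of another cell type numbered 84 in KO 1M, 2 in KO 2M and 56 in KO 4M. In KO 4M the 10 most abundant genes took 15.2% of UMIs, against 11.1% in Apoe 4M, and listed genes of the mitochondrial genome took 1.42%, against 2.74%. Which genes of the mitochondrial genome are listed differs between libraries, so these percents are not ranked over the 8 libraries.

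**Figure D3:**
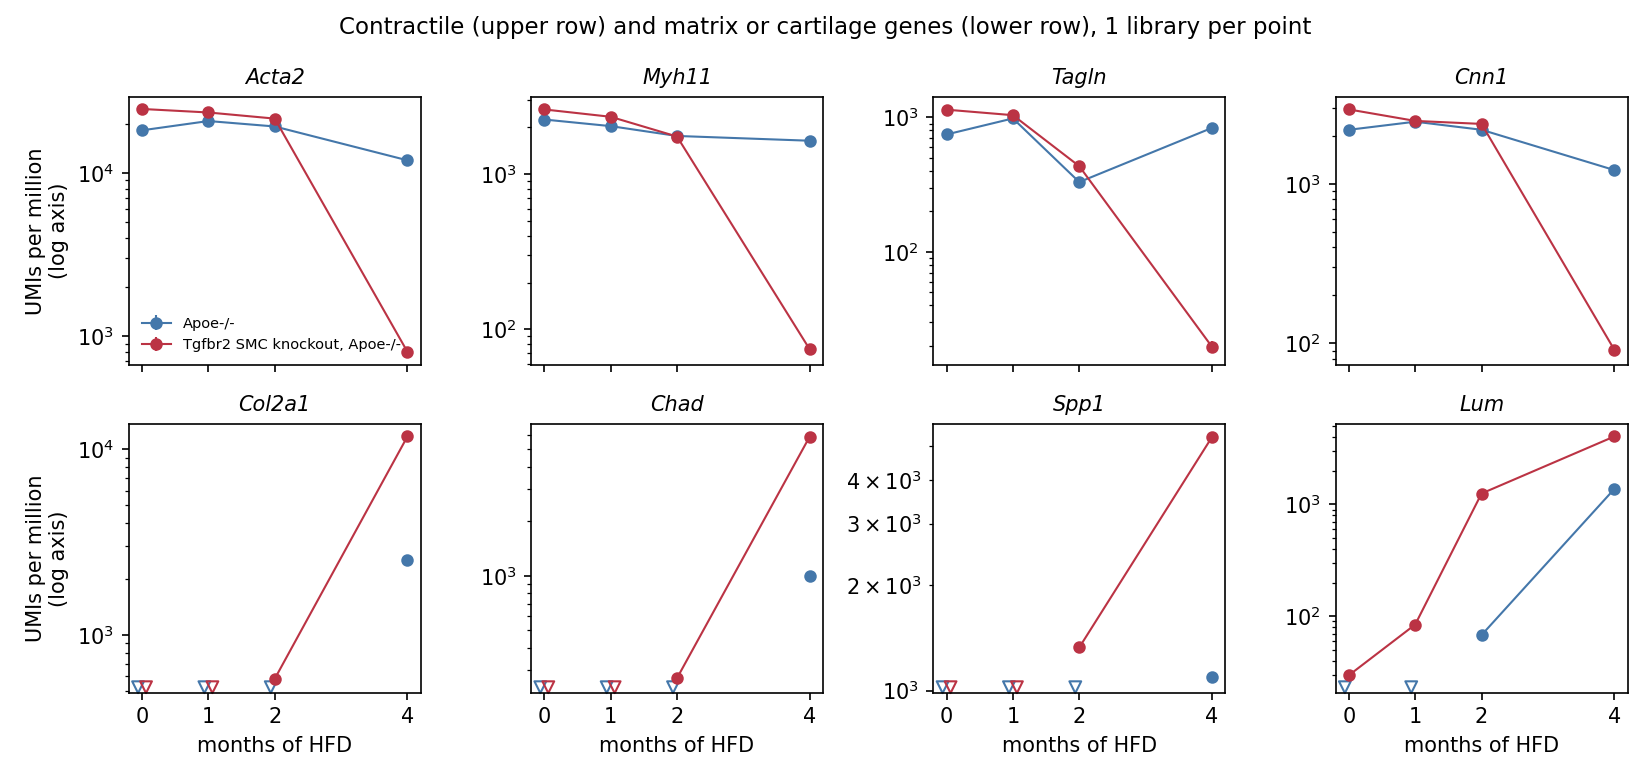
Levels as UMIs per 1000000 (CPM; y axis, log scale) against months of HFD (x axis, 0 for ND) for 4 contractile genes (upper panels) and 4 matrix or cartilage genes (lower panels). Each point is 1 library, error bars are exact Poisson 95% intervals and open triangles mark libraries where the gene is listed at 0; the contractile genes drop in KO at 4 months, where Col2a1 reaches 11749.

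The time-course tables asked what changed with months of HFD. A slope over months cannot tell the diet from the passing of time. In a slope common to both genotypes, Tpm1 (tropomyosin) fell by 0.48 ± 0.10 (SE) per month, Hspb6 by 0.41 ± 0.08 and Cav1 (caveolin 1, a protein of membrane caveolae) by 0.44 ± 0.08. Rasl11a fell by 0.45, Tinagl1 by 0.45, Rasl11b by 0.44, Eln by 0.40 ± 0.07, Cbr2 by 0.38, Mfap5 by 0.37 and Id2, a target of BMP and TGF-beta signalling, by 0.36 ± 0.04. Fth1, the ferritin heavy chain that stores iron, rose by 0.20 ± 0.02 per month, from 6891 to 15033 CPM in Apoe and from 7215 to 12346 in KO between ND and 4M. The complement genes C4b and C1ra rose by 0.16 ± 0.03 and 0.10 ± 0.01, and Tmem176b by 0.16 ± 0.02 (C4b and Tmem176b were listed at 0 in Apoe ND and Apoe 1M). Polr2l, Tcf4, Osmr (a receptor subunit for oncostatin M), Gas7, Htatip2 and Ly6e rose by 0.11, 0.09, 0.08, 0.07, 0.06 and 0.06; Gas7, Htatip2 and Ly6e were listed at 0 in Apoe ND.

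By limma, 514 of 9253 genes passed, 14 higher and 500 lower, with adjusted p for the named genes from 0.0289 (Mfap5) to 0.0499 (Cbr2). An unadjusted p under 0.05 was reached by 2632. Several choices end these calls: 0 genes passed without the libraries of any 1 diet (unadjusted 1414, 1459, 2230 and 2742 without ND, 1M, 2M and 4M), 0 on linear means, and 1 with cells thinned to 1 depth. With HFD against ND in place of months 0 passed by limma (unadjusted 424), and with rank of time 0 (2453). Without KO 4M alone 352 passed, 167 of them among the 514, and with the values of each library taken from its other table, 1346 passed, 513 of them shared.

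Among the lists, contractile genes had lower slopes than other genes (camera, adjusted p = 2.1e-04; adjusted p = 0.449 with an estimated correlation), with 2 of 17 past the threshold and 15 when adjusted over the list alone. Chondrocyte and bone genes had higher slopes than other genes (camera, adjusted p = 1.7e-07; adjusted p = 0.366 with an estimated correlation), though 0 of 17 passed, also when adjusted over the list alone. Slopes were also higher for the fibroblast list (0.00128; 0 of 6 and 4), the inflammatory list (0.00450; 1 of 8 and 2), the lipid handling list (0.0137; 1 of 12 and 1), the unfolded protein response list (0.0137; 0 of 11 and 0), the matrix-degrading list (0.0264; 0 up and 1 down of 9, 2 and 2) and the adipocyte list (0.0275; 0 of 5 and 2). Slopes were lower for oxidative phosphorylation (0.0137; 3 of 14 fell, 10 over the list alone) and the stress response (0.0137; 2 of 17 and 9). With an estimated correlation none of these held, with an adjusted p = 0.332 for the lowest and 0.497 for the highest of the 10 lists. By camera the TGF-beta-responsive, cholesterol synthesis and pericyte lists had an adjusted p of 0.244, mesenchymal stem cell 0.0956, interferon response 0.503, extracellular matrix 0.603 and mitochondrial genome 0.937. Fry called the TGF-beta-responsive, stress response and oxidative phosphorylation lists down (adjusted p = 0.00651 for each), and the pericyte list down (0.0417). It also called the inflammatory (0.0219) and fibroblast lists (0.0417) up.

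Within KO, slopes per month were -1.62 ± 0.31 for Acta2, -1.46 ± 0.29 for Myl9, -1.41 ± 0.31 for Tmsb4x, -1.25 ± 0.23 for Tpm2 and -1.11 ± 0.15 for Myh11. Col2a1 rose by 1.51 ± 0.32, Dcn by 1.503 ± 0.25, 1500015O10Rik (augurin) by 1.33 ± 0.28, Chad by 1.32 ± 0.29 and Lum by 1.31 ± 0.20. Adjusted p-values (limma) for these 10 genes ran from 0.0192 to 0.0372, and 2084 genes passed (629 higher, 1455 lower; unadjusted 4005). With trimmed-mean scaling 2371 passed (991 higher, 1380 lower), with cells thinned to 1 depth 815 (342 higher, 473 lower) and with rank of time in place of months 87 (1 higher, 86 lower). Col2a1 and Chad were listed at 0 in KO ND and KO 1M. Of the contractile list 16 of 17 members fell (camera, adjusted p = 3.2e-07), of the chondrocyte and bone list 15 of 17 rose (3.2e-07), and of the fibroblast list 4 of 6 rose (0.00819); adjusted over the list alone the counts were 16, 15, and 5 up with 1 down. The unfolded protein response list had higher slopes than other genes (0.00327; 2 of 11 rose, and 2 over the list alone), among them Herpud1 by 0.31 ± 0.06. The adjusted p = 0.446 with an estimated correlation for the first 3 of these lists and 0.463 for the last. These slopes rest on KO 4M: without it 0 genes passed (unadjusted 1537), and 0 passed without the ND or the 1M libraries.

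Within Apoe, limma called 0 genes (unadjusted 1165), and 0 on recovered UMI sums (615). The steepest slopes were those of Dcn (0.39 ± 0.25 per month, adjusted p = 0.604), Rpl35a-ps6 (0.38 ± 0.14), Lum (0.38 ± 0.20, listed at 0 in Apoe ND and Apoe 1M), Srpk1 (0.37 ± 0.09) and Gm29216 (0.37 ± 0.39) on the upper side and mt-Co3 (-0.58 ± 0.54, which rests on listings at 0 in Apoe 1M and Apoe 4M and is not read as a fall), Gadd45g (-0.45 ± 0.16), Gm4149 (-0.44 ± 0.29), Id3 (-0.37 ± 0.16) and Id2 (-0.36 ± 0.07, adjusted p = 0.253) on the lower. Between Apoe 2M and Apoe 4M Dcn went from 53.0 to 2451 CPM. Camera called 8 lists, all with a higher slope than other genes except oxidative phosphorylation and stress response: inflammatory (6.0e-05), chondrocyte and bone (1.3e-04), fibroblast (1.3e-04), lipid handling (0.00808), mesenchymal stem cell (0.00967), oxidative phosphorylation (0.00967), stress response (0.0376) and matrix-degrading (0.0406). None held with an estimated correlation (lowest adjusted p = 0.169), and the lipid handling median was -0.003, opposite in sign to its test.

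The slopes of the genotypes were compared directly in the interaction fit, where limma called 0 genes (unadjusted 1954), and 0 on recovered UMI sums (2313). Slopes were higher in KO than in Apoe for Col2a1 (difference 1.33 ± 0.45), Chad (1.19 ± 0.41), Cnmd (1.18 ± 0.37), Sparc (1.17 ± 0.43) and 1500015O10Rik (1.15 ± 0.40), of which Col2a1, Chad and Cnmd were listed at 0 in Apoe ND, 1M and 2M, and lower for Acta2 (-1.29 ± 0.44), Tmsb4x (-1.22 ± 0.43), Myl9 (-1.15 ± 0.40), Tpm2 (-0.97 ± 0.33) and Itih4 (-0.91 ± 0.21), all with an adjusted p of 0.226. As groups, contractile genes had lower slopes in KO (camera, adjusted p = 6.2e-09; 0 of 17 past, 15 when adjusted over the list alone) and chondrocyte and bone genes higher ones (2.5e-05; 0 of 17, and 13). The unfolded protein response list had higher slopes (0.00224; 0 of 11 by either count), and the interferon response (0.0192; 0 of 7) and mitochondrial genome lists (0.0467; 0 of 9, 2 over the list alone) lower ones. With an estimated correlation these 5 lists had an adjusted p = 0.618, so none held. Without KO 4M the difference for Acta2 was 0.01 and for Col2a1 -0.01.

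A Myh11 UMI was seen in 88.5% of Apoe 4M cells (95% interval 86.6 to 90.2) and in 13.0% of KO 4M cells (11.4 to 14.8), and with cells thinned to 2900 UMIs in 81.3% and 6.79%. Col2a1 was seen in 36.6% (33.9 to 39.4) and 99.9% (99.6 to 100), thinned 19.1% and 98.7%. In the largest Apoe 4M cluster of its time-course table (862 cells, median 7128 UMIs), 32.8% of cells had a Col2a1 UMI at 54.8 CPM, against 8985 CPM in the chondrocyte and bone-like cluster (281 cells, median 7524 UMIs). In KO 2M the largest cluster (2026 cells, median 7479 UMIs) had Col2a1 in 14.4% of cells at 20.2 CPM, against 10865 CPM in a cluster of 59 cells (median 15982 UMIs). Low expression and free RNA were not told apart for the cells of the largest clusters, so the Col2a1 shares of 36.6% in Apoe 4M and 17.0% in KO 2M are no counts of cartilage-like cells. Runx2, a bone transcription factor, was listed in KO 4M alone (34.6% of cells), and Ly6a (Sca1) in Apoe 4M (11.01%), KO 1M (5.07%), KO 2M (11.7%) and KO 4M (13.5%). Klf4 was seen in 83.5% to 94.8% of cells of every library, Lgals3 in 29.7% (Apoe ND) to 99.5% (KO 4M). Pparg was listed in the 4 KO libraries (6.91% to 23.0%), Cd68 in KO ND, KO 1M and KO 4M (5.64% to 7.91%) and Adipoq in none.

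Few markers of other cell types were listed, in cells sorted by a smooth muscle reporter. Of 16 macrophage markers 8 were listed in any library, of 11 endothelial markers 3, of 7 Schwann markers 1, and of 10 lymphocyte and 6 red blood cell markers 0. Of 14 cell cycle genes 6 were listed. These lists had too few measured genes to be tested. Pecam1 and Esam, expressed by endothelium, differed between genotypes by -0.14 and 0.03 (adjusted p = 0.529 and 0.738, limma), S100b by 0.32 (0.603), and the cell cycle genes Pcna and Tyms by 0.006 and 0.06 (0.928 and 0.339).

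Clustering gave 42 clusters in the 6 tables, of which 40 drew over 90% of their cells from 1 library and 11 could be named from markers, so that a cluster here can be a library and not a cell type. Beside these sizes stands the sort for GFP. By the KO time-course table, 91.8% of KO 4M cells (95% interval 90.4 to 93.1) were in 2 chondrocyte and bone-like clusters, and 8.18% were unnamed. By the Apoe time-course table, 22.8% of Apoe 4M cells (20.4 to 25.2) were chondrocyte and bone-like and 77.2% unnamed; by the 4M table, 3.72% of Apoe 4M cells had that name, 70.8% were contractile-like and 25.5% unnamed, and all KO 4M cells were unnamed, while other settings of that table named 56.2% (resolution 0.3), 24.4% (resolution 1.0) and 31.6% (1000 variable genes) of KO 4M cells chondrocyte and bone-like, and 0% on genes listed for every library. By the 2M table, 8.17% of KO 2M cells (7.07 to 9.38) were chondrocyte and bone-like and 44.4% contractile-like (Apoe 2M 0.113%). No other setting of that table gave the contractile-like name. Of Apoe 2M cells, however, 26.5% were contractile-like by the Apoe time-course table. There the share was 27.6% with 1000 variable genes and 30.1% on genes listed for every library. No Apoe 2M cell had that name there at resolution 0.3 or 1.0. The KO time-course table gave KO 2M cells that name only on genes listed for every library (32.5%). By the 1M table, 3.15% of KO 1M cells were fibroblast-like (41 cells), 0.998% macrophage-like (13 cells, with Lyz2 at 8757 CPM) and 95.9% unnamed. No ND cell of the ND table was named. Shares depended on the table and on the setting. The chondrocyte and bone-like share of KO 2M (8.17%) was read from the 2M table alone. That of KO 4M, in its time-course table, was 55.6% at resolution 1.0 and 40.2% with 1000 variable genes. That of Apoe 4M, in its time-course table, was 4.13% at resolution 0.3.

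In pairs of libraries of equal cell number, 57.3% to 84.3% of the 15 nearest neighbours of a cell came from its own library when both had 1 genotype and diets up to 2M, 86.9% to 98.7% when 1 of them was a 4M library of that genotype, and 96.2% to 97.9% when they had 2 genotypes on 1 diet.

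**Figure D4:**
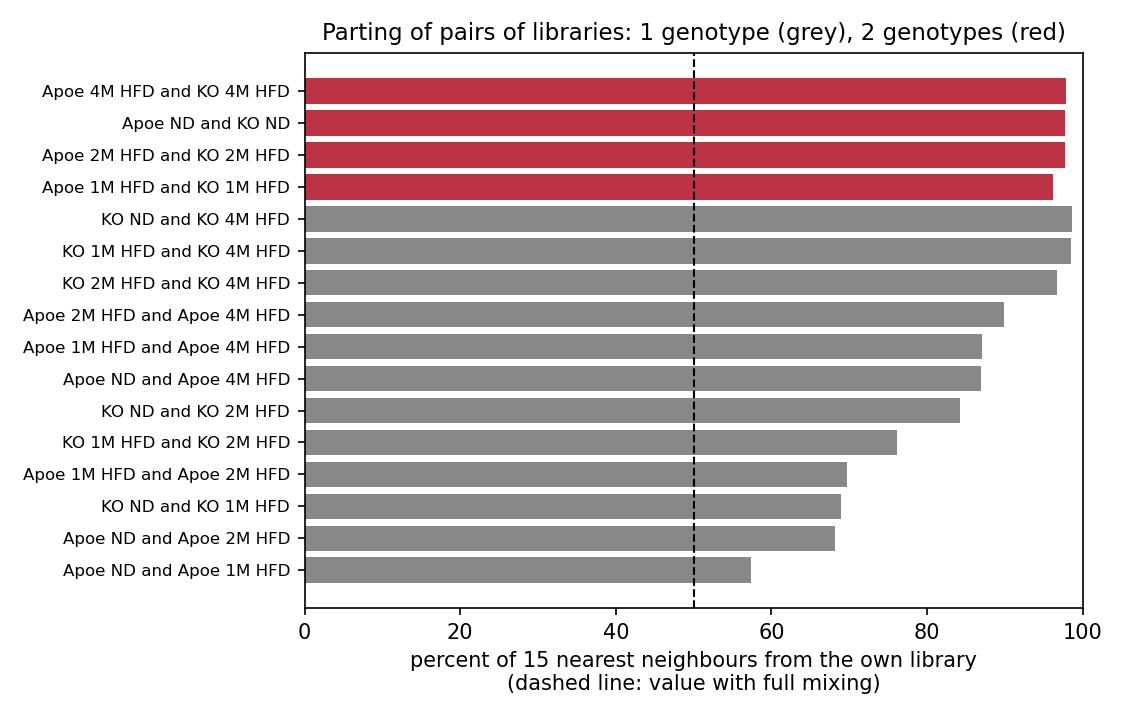
Percent of the 15 nearest neighbours of a cell that came from its own library (x axis) for pairs of libraries with equal numbers of cells (y axis). Grey bars are pairs of 1 genotype, red bars pairs of 2 genotypes on 1 diet, and the dashed line is the value with full mixing; the 4 red bars lie between 96.2 and 97.9.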

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

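All tests of explanations for KO 4M in this part were chosen after the result was seen, except the test for free RNA; the counts over other orders and swaps of the libraries were also chosen afterwards. The slopes of 5 fixed lists differed between genotypes by a test of the difference itself (camera on the difference of slopes): contractile (adjusted p = 6.2e-09, lower in KO), chondrocyte and bone (2.5e-05, higher), unfolded protein response (0.00224, higher), interferon response (0.0192, lower) and mitochondrial genome (0.0467, lower). With an estimated correlation the adjusted p = 0.618 for each, and fry gave 0.216 to 0.312. No single gene passed in limma (unadjusted 1954; UMI sums 0), and 8 of the 8 swaps of genotypes within diets gave 0, too few swaps for a share under 0.05.

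In KO 4M Acta2 stood at 802 CPM and Col2a1 at 11749. Without KO 4M their differences of slopes were 0.01 and -0.01; no list was tested without it. A depth difference is argued against: with every cell thinned to 1 depth, 98.7% of KO 4M cells kept a Col2a1 UMI. For free RNA as the whole source of the contractile UMIs in chondrocyte-like cells, the gene ratios were compared with those of the other KO 4M cells. The share of these UMIs differed by over 2-fold for 2 of 6 genes and stayed within 2-fold for the others. These were Tagln (ratio 0.422 on 33 UMIs) and Actg2 (ratio 0.499921, only just past the bound). That argues only against free RNA with the ratios of those other cells. Free RNA with other ratios was not tested, so free RNA stays open. A mislabelled sample cannot be told apart: 63.3% of the 240 genes called on the other diets kept the KO sign at 4M (113 of 150 lower, 39 of 90 higher), against 51.9% of all genes. Cells of another origin in the sort stay open too, since 0 reporter transcripts are listed; a change of smooth muscle cells toward a chondrocyte-like state, as a possible explanation, stays open as untested. Cells named chondrocyte and bone-like were also 22.8% of Apoe 4M (Apoe time-course table) and 8.17% of KO 2M (2M table). Both shares depend on the table or the setting: that of Apoe 4M was lower by the 4M table, and that of KO 2M was lower at resolution 1.0.

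Tgfbr2 UMIs appeared outside the compared values. The Apoe time-course table holds 582 (ND), 588 (1M), 774 (2M) and 514 (4M) Tgfbr2 UMIs, although the file names say that the gene was removed, while the KO tables list none. Since genes under 5% of cells are also listed at 0, the difference between genotypes was not tested.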

How the results depend on the processing

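Tests chosen after the data were seen: linear means plus 1, UMI sums, thinned cells, genes listed in all 8 libraries, the fits without KO 4M, clusters on genes listed for every library and, for the slopes within a genotype, all settings but pseudocounts of 0.1 and 10. The planned filter at 500 genes per cell removed no cell and a count test was not run, since the values are logs.

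Genotype effect (14 genes: 2 higher, 12 lower). Linear means plus 0.1, 1 and 10 gave 9 (1, 8), 4 (1, 3) and 0 (unadjusted 1123), trimmed-mean factors 4 (1, 3), values not rescaled 11 (4, 7), UMI sums 1, no diet term 11 (1, 10) and genes listed in all 8 libraries 8. With no diet term only 4 of the 11 were among the 14. Thinned cells gave 15 (1, 14), of which 7 were among the 14. Leave-one-out gave 1 without ND, 0 without 1M (unadjusted 844), 0 without 2M (701) and 240 (90, 150) without 4M. Months slope (514: 14, 500). Linear means plus 0.1, 1 and 10, trimmed-mean factors, values not rescaled, HFD against ND and rank of time gave 0 each by limma (unadjusted 1980, 2154, 2379, 2150, 2444, 424 and 2453), as did leave-one-out of ND, 1M, 2M and 4M (1414, 1459, 2230 and 2742). UMI sums and thinned cells gave 1 each, 1346 (25, 1321) passed with values from the other tables and 352 without KO 4M. Difference of slopes (0): 7 (1, 6) without 2M and 0 without ND (1723), 1M (431), 4M (458) or KO 4M (555). Apoe slope (0): 1 without KO 4M. KO slope (2084: 629, 1455): 0 without ND, 1M, 4M or KO 4M (3144, 1974, 1890 and 1537), 87 with rank of time, 815 (342, 473) with thinned cells. The split also moved with trimmed-mean factors (991, 1380), robust limma (1037, 1773), without 2M (3060: 1210, 1850) and with the other tables (332, 1590).

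Single diets with 10 added: 109, 75, 155 and 1245 genes from ND to 4M. Lists: camera with an estimated correlation called 0 in all 5 comparisons and fry called 3, 6, 0, 0 and 8 (genotype, months, difference, Apoe, KO), against 5, 10, 5, 8 and 4. Clusters: the chondrocyte and bone-like share was 55.6% (resolution 1.0) and 40.2% (1000 genes) in KO 4M, 4.13% (resolution 0.3) in Apoe 4M and 2.80% (resolution 1.0) in KO 2M; the contractile-like share of Apoe 4M was 75.9% (resolution 0.3). Shares at 2 times the smallest value and thinned: Myh11 82.8% and 81.3% in Apoe 4M, 5.96% and 6.79% in KO 4M; Col2a1 11.9% and 19.1% in Apoe 4M, and 98.7% thinned in KO 4M.

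Signs reversed for 16 values that no test had called, in 15 results. Leaving out libraries gave these ranges for slopes in Apoe, with the reversed end without both 4M libraries: Dcn -0.00704 to 0.547, Rpl35a-ps6 -0.118 to 0.548, Gm29216 -0.0908 to 0.554, mt-Co3 (listed at 0 in Apoe 1M and 4M) -0.849 to 0.0304, Gadd45g -0.645 to 0.0595 and Id3 -0.507 to 0.00898. Gm4149 ran from -1.439 (without 4M) to 0.1496 (without ND). Differences of slopes reversed without KO 4M: Col2a1 -0.0124 to 1.81, Chad -0.0253 to 1.625, 1500015O10Rik -0.0361 to 1.56, Acta2 -1.65 to 0.0109, Tmsb4x -1.601 to 0.0541, Myl9 -1.54 to 0.0638 and Tpm2 -1.27 to 0.00497. Sparc ran from -0.0901 (without both 4M libraries; -0.07 without KO 4M) to 1.67. Of values of named genes, 225 of 356 kept their sign and their side of the threshold for the genotype effect. The others kept their sign but lost (122) or gained (9) a call. For the months slope 108 of 391 kept both and 283 lost a call only, and in KO 123 of 184 kept both and 61 lost a call only. For the difference 174 of 183 and in Apoe 181 of 188 kept both, and the others reversed in sign. Of 218 shares of cells 199 moved beyond their interval.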

Other observations

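The tests for escape from the deletion, in the form split by library, and for doublets, the tests of genes listed for only some libraries, of all steps together by table and of batches, and the counts over other splits were chosen after the result was seen. The genes named next were chosen after their values were seen. A small cluster of the KO time-course table had high levels of Eln and Fbln5, which were low in other KO cells. In KO 1M (45 cells) it held Eln at 9291 CPM, against 161 in the largest KO 1M cluster, Mfap4 at 4967 against 100.2 and Fbln5 at 2127 against 50.2. Its Ly6a (Sca1) stood at 329 against 4.19, Dcn at 5051 against 43.5 and Acta2 at 2422 against 24771. In KO 2M (158 cells) it held Eln at 2269 against 214, Fbln5 at 987 against 113, Lum at 9639 against 361, Vcam1, an adhesion molecule, at 2069 against 465 and Mmp3, a matrix protease, at 1680 against 25.1. In KO 4M (129 cells) it kept Acta2 at 10597 and Myh11 at 1111, while the 2 chondrocyte and bone-like clusters had Acta2 at 149 and 246. It made up 0.177% of KO ND, 3.46% of KO 1M, 7.01% of KO 2M and 8.18% of KO 4M cells; its cells carry no marker name at this setting, and sizes of clusters defined by such genes are no measure of growth.

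Doublets could explain a mixed profile, but the cluster's cells held 0.913 times the median UMIs of their library. Cells that escaped the deletion might keep Eln. Of the genes called lower in KO without the 4M libraries, 43.75% were higher in the cluster's KO 2M cells (63 of 144; 95% interval 35.5 to 52.3), against 42.0% of all genes, and of those called higher 72.2% were lower (65 of 90), against 58.0%. In KO 1M the shares were 59.5% (88 of 148; 51.1 to 67.4), against 41.2%, and 71.1% (64 of 90), against 58.8%. In KO 2M the lower genes, whose interval lies under 60%, went against escape of all the cluster's cells, while the higher genes went with it. The interval treats genes of 1 library as independent and the bound of 60% was set afterwards, so the test does not decide. For the 45 cells of KO 1M escape cannot be told apart, as 59.5% lies too near that bound. Escape of some cells, and cells of another lineage that the sort let through, stay open as untested. The latter is not set aside by names at other settings: a cluster led by Ly6a was mesenchymal stem cell-like at resolution 1.0 (298 cells) and on genes listed for every library (316 cells), and the 1M table had 41 fibroblast-like KO 1M cells led by Dcn and Lum. Whether these are the same cells was not tested.

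In KO 1M 13 macrophage-like cells (median 9862 UMIs) held Lyz2 at 8757 CPM and still had Acta2 in 100% of cells at 2313, so a level near 2313 for a gene as abundant as Acta2 may be background there. In KO 4M thinning left Acta2 in 34.4% of cells.

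Cells parted by library in all 6 tables. Of the technical sources tested on genes and depth, none explained all of it alone. The percent of neighbours from the own library was 96.8 (KO) and 97.0 (Apoe) in the time-course tables with all genes, where chance gives 26.9 and 27.7. Its lowest value was 89.3 on genes listed for every library and 93.1 at 1 depth. Without genes that share reads (pseudogenes, ribosomal and mitochondrial genes) it was 75.4, in the Apoe time-course table, with the lowest library at 61.7. Such genes thus carried part of the parting there. With all of these steps together the percent was 55.4 in the Apoe time-course table, so their joint effect cannot be told apart there. The other 5 tables stayed at 75.9 (KO time-course table, lowest library 62.2) or above (96.4 or more in the diet tables). That argues against the joint effect as the whole cause in those 5. Pairs of 1 genotype on different diets up to 2M had a median of 69.3, below every pair of 2 genotypes. Pairs of KO 4M with another KO library reached 96.7 to 98.7, within or above the range of pairs of 2 genotypes. Up to 2M libraries of 1 genotype thus parted less than genotypes did. With 1 library per group, batches of single libraries still cannot be told apart. A batch shared by all libraries of a genotype could also part the genotypes, and a genotype effect stays open beside it.

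Other splits and orders of the libraries gave few calls. For the genotype effect 1 of 32 splits, the real one, gave 14 genes and the highest other gave 0. Only 8 of these splits part the 2 libraries of every diet, as the real one does. Among them 1 of 8 gave as many, which is the smallest share possible, so this count cannot fall under 0.05. For the months slope 1 of 100 orders gave as many as 514, with 41 the highest other. For the slope in KO 1 of 24 orders gave 2084, with 40 the highest other, and 1 of 24 is the smallest share possible. For the slope in Apoe 24 of 24 orders gave 0, so the count decides nothing.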
